A study of Mus musculus with 4 samples.

How the data were processed

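Bulk RNA sequencing of basal epithelial cells sorted from the ventral lobe of the mouse prostate was analysed in 4 libraries, 2 from the distal tips of the gland and 2 from its ducts. Per the labels, lobes of 20 mice were cut into tips and ducts, cells positive for CD45, CD31 or CD140a (the products of Ptprc, Pecam1 and Pdgfra) were removed in the sort, and basal cells were gated as high for both EpCAM and CD49f (the product of Itga6). RNA was extracted with a micro-column kit and libraries were made with the Ovation SoLo system, a low-input RNA-seq kit. The submitters' processing notes name STAR, HTSeq and the mouse build GRCm38 (mm10). Versions, the annotation release and the strand setting of the counting are not given in the sources used here. The groups were taken from the titles, because the cell type field describes all 4 libraries as tip. The titles give the age as postnatal day 13, whereas the age field gives days 10 to 12. Luminal cells, which the design also mentions, were not analysed here. The labels do not say that the 2 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

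The authors' deposited signal is a read count per gene scaled to a common library total and rounded up to a whole number, as found from the values themselves, with deposited totals of 20008326 to 20011820. One table held 49671 genes with Ensembl identifiers, and 101 symbols were shared by 2 or more identifiers. Within each library the values were multiples of a single step, and dividing by that step gave whole reads, within 0.1 read, for at least 99.995% of values. Scaling those reads and rounding up gave back at least 99.88% of the deposited values exactly. The recovered totals were 1439003 reads in tip 1, 1742531 in tip 2, 1568194 in duct 1 and 1517982 in duct 2. One read was worth 0.574 to 0.695 CPM (reads per 1000000 reads of a library), and the limit that a count of 0 allows, 3 reads, was 2.08, 1.72, 1.91 and 1.98 CPM in the same order. Floors and counting intervals cover counting error only, since reads were not traced to single molecules. Between 21008 and 21557 genes had a read in a library. The design chosen before the data were examined allowed for raw counts or scaled values, and the scaled form applied. No library pair agreed within sampling noise: chi-square per degree of freedom ran from 6.88 for the tips to 20.8 for the ducts.

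Deposited values were divided by 20 to give CPM. Genes with a mean of at least 1 CPM over the 4 libraries were tested (17865 genes). The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a variance trend and robust moderation, tip against duct, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. Separately, genes were counted whose lower value in one group was at least 2 times the higher value in the other. An exact permutation test of 2 libraries against 2 cannot give a 2-sided p under 0.333. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

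The steps were tested on simulated reads for this comparison with 200 of 17865 genes changed. At an adjusted p of 0.05, limma recovered 0.5% of genes changed 2-fold, 0 of those changed 4-fold, 80% of those changed 8-fold and 94% of those changed 16-fold. At 8-fold and 16-fold it also called 19 and 22 unchanged genes. Each gene was drawn independently around its mean over all libraries. Differences shared by many genes within a library were not simulated, so these rates need not hold for the real libraries.

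Before the data were examined, 37 gene lists were fixed for cell types, matrix, adhesion, proliferation, signalling, differentiation, metabolism, immune signalling and RNA quality. Lists with at least 5 tested members (36) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. That correlation was estimated from 2 libraries per group, and only the preset form was run on simulated reads. A list that fails with an estimated correlation is therefore not shown to be unchanged. The red cell list was left out for having too few tested members. Named genes followed a rule fixed at the same time. It took up to 8 genes per direction by fold among those past the threshold with non-overlapping groups and at least 5 CPM in the higher group, leaving out predicted and pseudogene models. Where fewer passed, it was filled with the smallest p among non-overlapping genes, to which the same level and symbol requirements were applied. It also took 20 check genes, and 2 to 4 members of each list described, by smallest p where none passed. Which lists to describe with member genes was chosen after the list results were seen. The text does not print every gene that this rule takes.

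Alternatives were TMM, median-ratio and quantile scaling, a total without mitochondrially encoded and the 10 most abundant genes, pseudocounts of 0.25 and 4 CPM, no filter or a mean of at least 5 CPM, other variance models, voom, edgeR and DESeq2, other thresholds, the title number as a block, and leaving out each library. A covariate for fibroblast marker level, and checks of it with other splits and other covariates, were added after the data were seen. Identifiers were looked up in GENCODE M21 (GRCm38), where 49412 of the 49671 matched, and coordinates come from that annotation.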

Results

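The data comprise 4 RNA-seq libraries of sorted basal cells, the outer p63-positive layer of the prostate epithelium, from the ventral lobe of young male mice. There were 2 libraries from gland tips and 2 from ducts, with 1439003 and 1742531 recovered reads in tip and 1568194 and 1517982 in duct. The comparison asks how basal cells at the tips differ in expression from those in the ducts, in a study concerned with collagen signalling, matrix stiffness and the potency of these cells.

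Ccnb1, which encodes the mitotic cyclin B1, measured 11.2 and 15.5 CPM in the tip libraries and 0.65 and 0 CPM in the duct libraries. Scnn1g, a subunit of the epithelial sodium channel, averaged 63.8 ± 17.9 CPM in tip and 14.9 ± 1.27 CPM in duct (SD, n = 2 each). Alad, an enzyme of heme synthesis, averaged 44.9 ± 0.601 against 11.02 ± 0.672 CPM, and Fads1, a fatty acid desaturase, 102.4 ± 3.57 against 34.7 ± 3.08 CPM. In the other direction, Gbp2, an interferon-inducible GTPase, averaged 16.1 ± 0.849 CPM in tip and 94.1 ± 39.3 CPM in duct, and Emp1, an epithelial membrane protein, 456.1 ± 213.6 against 1444 ± 127 CPM.

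No gene passed the adjusted threshold in limma, where the smallest adjusted p was 0.667, so these genes are given as values and not as changes. At an unadjusted p under 0.05 limma counted 1039 genes higher and 287 lower in tip (1326 in all, with 893 expected by chance). With TMM scaling the counts were 570 and 540. At the same level, tip 1 and duct 1 against tip 2 and duct 2 gave 1090 genes, and tip 1 and duct 2 against tip 2 and duct 1 gave 469. edgeR on the recovered reads also called 0 genes, with 1058 at an unadjusted p under 0.05, and voom called 0 with 1014. Without the filter on low values limma called 62 genes higher and 32 lower. DESeq2 called 2 genes lower in tip, with 416 at an unadjusted p under 0.05. They were Gbp2 (adjusted p = 0.0131, and 1.0e-05 to 0.999 over 19 alternatives) and, chosen here after its values were seen, Ins2 (adjusted p = 0.0131, and 2.6e-12 to 1), which had 204.9 CPM in duct 2 and 0 in the other 3 libraries.

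Of the 8 genes that the rule took as higher in tip, the remaining 4 were Tril (log2 fold 2.11 ± 0.42, SE), Trpm3 (1.38 ± 0.28), Pdgfa (1.57 ± 0.32) and Spon2 (1.85 ± 0.38). Pdgfa, which encodes a platelet-derived growth factor chain, measured 318 and 196 CPM in tip and 93.2 and 75.1 CPM in duct. Of the 8 taken as lower, the remaining 6 were Zdbf2 (-1.51 ± 0.28), Sbno2 (-1.49 ± 0.29), Clic4 (-1.30 ± 0.26), Mical2 (-1.62 ± 0.33), Pmepa1 (-1.65 ± 0.34) and Rras2 (-1.41 ± 0.32). Mical2, an actin-oxidising enzyme, measured 22.2 and 24.1 CPM in tip and 81.0 and 66.5 CPM in duct. Ccnb1 rested on 43 tip and 1 duct reads, a ratio of 41.7 with a 95% counting interval of 7.10 to 1685. Ccnb1 lies on chromosome 13 at 100778650 to 100786570, and Gbp2 on chromosome 3 at 142620602 to 142638008 (GRCm38). Tril, Trpm3, Pdgfa, Gbp2 and Zdbf2 overlap annotated exons on the opposite strand, and Gbp2 belongs to a family of similar sequence, so their counts are uncertain to that extent.

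**Figure D1:**
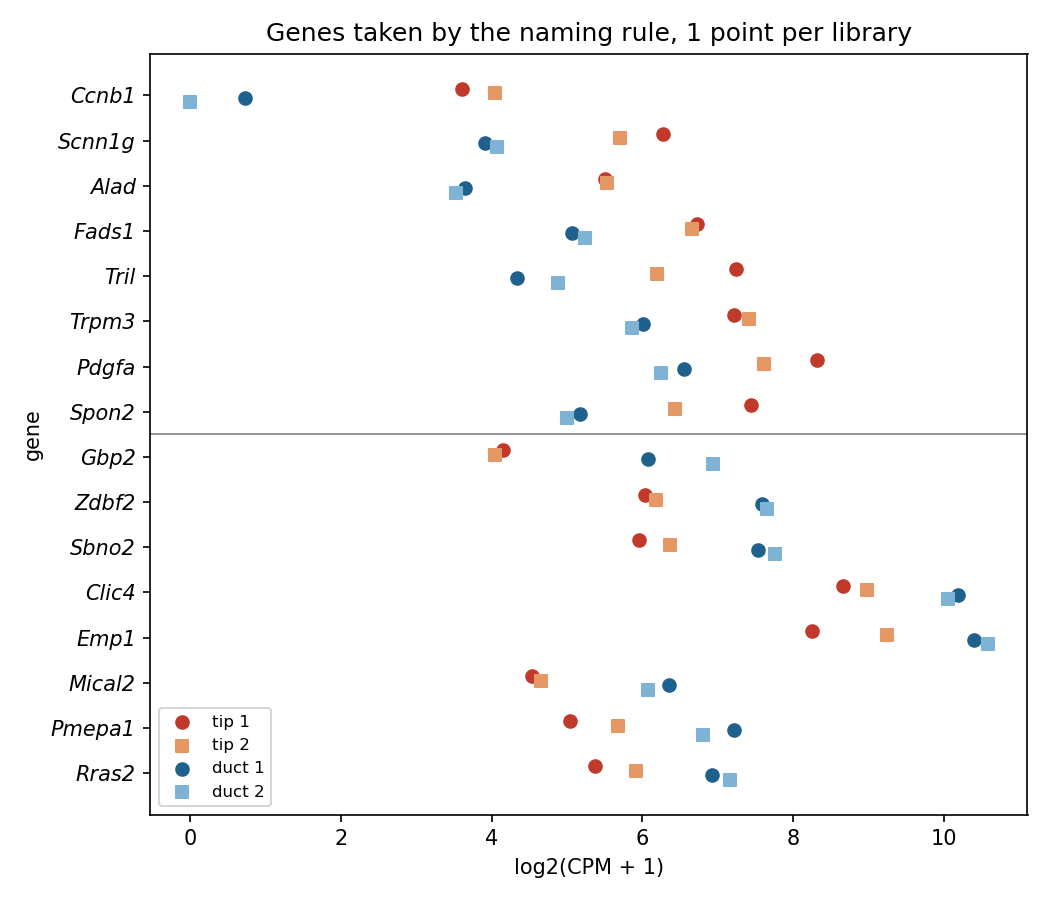
Each row is a gene taken by the naming rule and each point a library, with log2(CPM + 1) on the horizontal axis and small vertical offsets to keep points apart. Above the line both tip libraries exceed both duct libraries, as for Pdgfa at 318 and 196 against 93.2 and 75.1 CPM, and below the line they lie under them.

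The direction of the whole distribution depended on scaling. The median gene was 0.20 higher in tip on the log2 scale with the deposited scaling, 0.03 with TMM and -0.01 with median-ratio factors. Among genes at an unadjusted p under 0.05, the share higher in tip was 78.4% as deposited, 51.4% with TMM, 45.2% with median-ratio and 53.2% with quantile scaling. With TMM the rule genes stood at log2 folds of 1.18 to 3.36 and -2.61 to -1.50.

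By a count that needs no variance model, 653 genes were at least 2-fold higher in both tip libraries than in both duct libraries, and 236 at least 2-fold lower. With TMM scaling these counts were 416 and 363. The total of 889 lay between those of the other ways to split the libraries, 957 for tip 1 and duct 1 against tip 2 and duct 2, and 659 for tip 1 and duct 2 against the rest. Groups did not overlap for 39.7% of tested genes, where chance gives 33.3%. Of the 17865 tested genes, 5099 were higher and 1986 lower in both tip libraries. With the deposited scaling 63.1% of tested genes had a positive log2 fold, and 51.7% with TMM. Member counts of the gene lists below are to be read against these shares.

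Mitosis genes ranked higher in tip than other genes did. Of 27 tested members, 25 had a positive log2 fold and 15 were higher in both tip libraries than in both duct libraries, with a median of 0.89 (0.69 above the median gene). The camera adjusted p was 2.5e-04 with the preset correlation and 0.917 with an estimated correlation. No member passed over all genes, and 3 passed adjusted over the list alone: Ccnb1, Cenpe, a kinetochore motor (24.8 ± 10.4 against 4.60 ± 3.75 CPM, SD, n = 2), and Anln, the cytokinesis protein anillin (33.8 ± 6.54 against 9.17 ± 5.69 CPM). Mki67, the gene of the Ki-67 antigen, measured 81.3 and 180 CPM in tip and 9.60 and 60.6 CPM in duct. The mean deviation of the list from its 4-library mean was 0.18, 0.88, -0.99 and -0.07 (log2) in tip 1, tip 2, duct 1 and duct 2, beside -0.46, 0.75, -1.83 and 1.55 for fibroblast markers. Over 11 alternatives the adjusted p ran from 9.9e-09 to 0.917, with 0.222 without tip 2 and 0.134 without duct 1.

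DNA replication genes also ranked higher in tip. Of 26 members, 23 had a positive log2 fold and 12 were higher in both tip libraries, with a median of 0.63. The camera adjusted p was 0.0141 with the preset correlation and 0.917 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The helicase subunit Mcm4 measured 68.2 and 63.1 CPM in tip against 22.3 and 31.6 CPM in duct, Hells 25.7 and 28.7 against 8.30 and 10.5 CPM, and Dtl 58.4 and 35.6 against 19.1 and 20.4 CPM. Over 11 alternatives the adjusted p ran from 0.00665 to 0.917. It was 0.0581, 0.0511 and 0.192 without tip 1, tip 2 and duct 1 in turn, and 0.116 with a mean of at least 5 CPM.

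Oxidative phosphorylation genes were the third list higher in tip, with 25 of 27 members positive, 17 higher in both tip libraries and a median of 0.37 (0.17 above the median gene). Cycs was lower in both tip libraries (15.3 and 18.95 against 30 and 22.4 CPM). The camera adjusted p was 0.0428 with the preset correlation and 0.917 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Sdhb, of the succinate dehydrogenase complex, averaged 37.2 ± 1.45 against 13.3 ± 2.93 CPM (SD, n = 2), Uqcrc1, of complex III, 103.2 ± 3.39 against 53.0 ± 14.3 CPM, and Ndufs7, of complex I, 21.7 ± 0.707 against 10.1 ± 0.247 CPM. Over 11 alternatives the adjusted p ran from 0.0107 to 0.917, with 0.119 under TMM scaling, 0.0814 with a mean of at least 5 CPM and 0.0859 with the title number as a block. It was 0.0668, 0.194 and 0.262 without tip 1, tip 2 and duct 2 in turn.

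Focal adhesion and mechanosensing genes ranked lower in tip. Of 35 members, 22 had a negative log2 fold, 9 were lower and 4 higher in both tip libraries, and the median was -0.16. The camera adjusted p was 0.0141 with the preset correlation and 0.917 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Piezo1, a stretch-activated ion channel, measured 99.4 and 187 CPM in tip against 226 and 374 CPM in duct, whereas Tns3 measured 787 and 351 against 275.5 and 175 CPM. Over 11 alternatives the adjusted p ran from 0.00129 to 0.917, with 0.161 without tip 1 and 0.134 without duct 1.

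Interferon-stimulated genes and markers of neural, glial and neuroendocrine cells ranked lower in tip, and for both the adjusted p was 0.0141 with the preset correlation and 0.917 with an estimated correlation. The interferon list had a preset p of 0.0013 for tip against duct and 3.0e-06 for tip 1 and duct 2 against tip 2 and duct 1, a split in which immune (3.4e-10) and endothelial markers (6.7e-08) also separated. The neural list had 9.95e-04 for tip against duct and 1.6e-04 for tip 1 and duct 1 against tip 2 and duct 2. Of 24 interferon-stimulated genes 19 had a negative log2 fold (median -0.33), but 2 were lower in both tip libraries. Gbp2 was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. Oasl2 measured 67.4 and 39.6 CPM in tip against 46.6 and 18.4 CPM in duct, and Gbp3 7.65 and 5.75 against 6.40 and 23.1 CPM. For the interferon list the adjusted p ran from 1.1e-05 to 0.917 over 11 alternatives, and was 0.608 without tip 2, 0.48 without duct 2 and 0.0814 with a mean of at least 5 CPM. Of the 8 neural markers 7 had a negative log2 fold (median -0.76), and duct 2 stood 1.497 (log2) above the 4-library mean. Of these 8, Scg2, Chga (2.10 and 1.15 against 0.65 and 13.2 CPM) and Chgb (0 and 1.15 against 0 and 4 CPM), the last 2 chosen after their values were seen, are also expressed in pancreatic islets, and duct 2 alone held reads of Ins2 (311), Ins1 (86) and Iapp (102). Sox10 measured 5.60 and 2.90 CPM in tip against 3.2 and 24.4 CPM in duct, and Scg2 had 9.25 CPM in duct 2 and 0 in the others. No neural marker passed over all genes or adjusted over the list alone. Without duct 2 this list turned to higher in tip (adjusted p = 0.912), and without tip 1 the adjusted p was 0.0614, within a range of 1.4e-07 to 0.917 over 10 alternatives.

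With an estimated correlation, 0 of the 36 lists passed, the smallest adjusted p being 0.917, and 0 passed with fry. Whether these tests could pass a changed list with 2 libraries per group was not simulated. The preset test also passed 16 and 14 lists in the other ways to split the 4 libraries, against 6 for tip and duct.

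**Figure D2:**
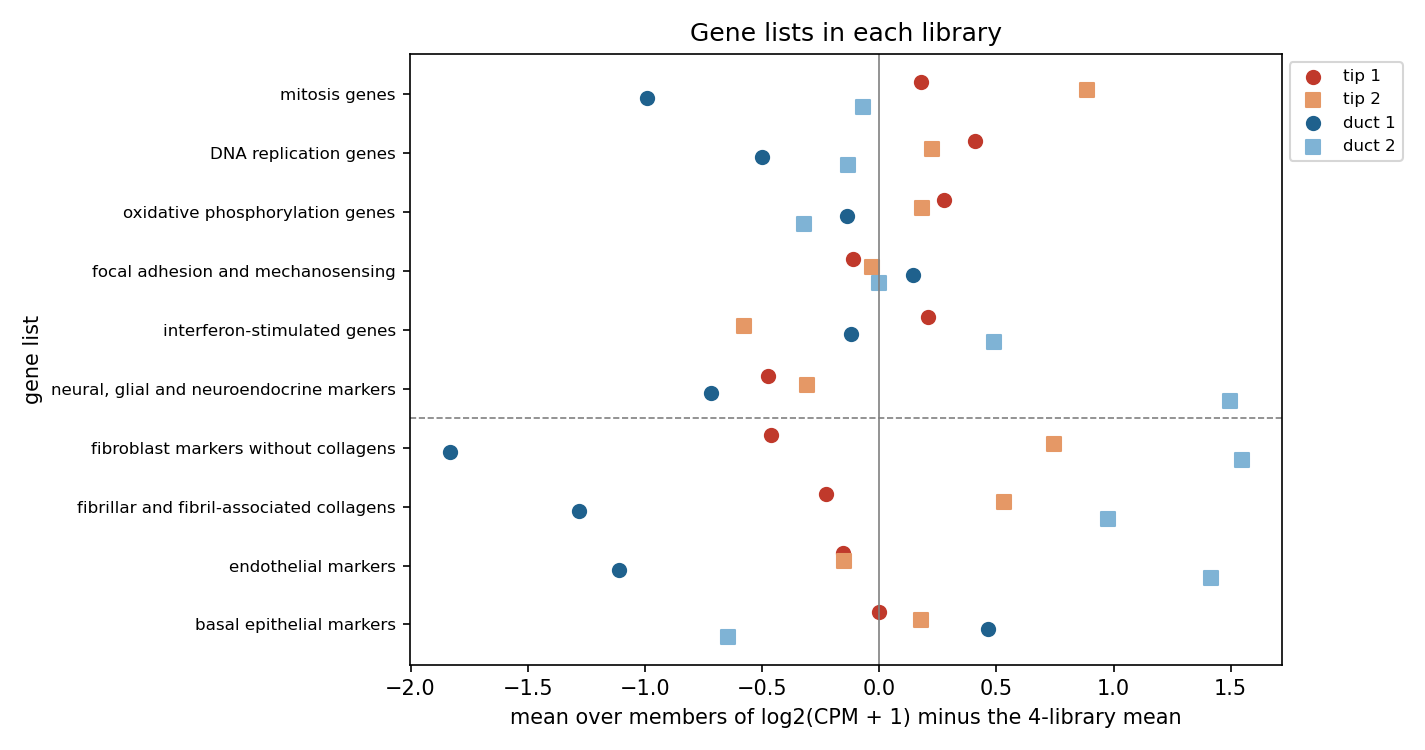
Each row is a gene list and each point a library, placed at the mean over members of log2(CPM + 1) minus the 4-library mean, with small vertical offsets to keep points apart. Above the dashed line are the 6 lists past the preset test; below it fibroblast markers run from -1.83 in duct 1 to 1.55 in duct 2.

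Among the check genes, those of the sort did not separate tip from duct. Epcam measured 138 and 227 CPM in tip and 483 and 159 CPM in duct, and Itga6 1177 and 939 against 1389 and 474 CPM. Of the markers removed in the sort, Ptprc measured 12.6 and 0.60 against 0.65 and 4.65 CPM, Pecam1 31.3 and 25.3 against 12.2 and 62.6 CPM, and Pdgfra 193 and 231 against 42.1 and 650 CPM. Basal keratin Krt14 (599 and 686 against 1744 and 512 CPM) and the luminal keratins Krt8 (226 and 322 against 721 and 246 CPM) and Krt18 (339 and 379 against 814 and 304 CPM) overlapped. Krt5 (650 and 513 against 490 and 148 CPM) and Trp63 (830 and 281 against 263 and 136 CPM) were higher in both tip libraries with the deposited scaling, without passing the test. Dividing by the TMM factors (1.03 for tip 2, 0.954 for duct 1) puts tip 2 below duct 1 for both genes. Itgb1, the beta subunit of collagen-binding integrins, measured 641 and 802 against 834 and 946 CPM. Jun measured 2066 and 1284 against 998 and 885 CPM, and Fos 3574 and 1304 against 1512 and 1221 CPM.

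Collagen transcripts differed more within groups than between them. Col1a1 measured 956 and 3361 CPM in tip against 274 and 5922 CPM in duct, Col1a2 659 and 2056 against 154 and 3826 CPM, and Col3a1 1126 and 2935 against 324 and 5969 CPM. Their log2 folds were 0.49 ± 1.93, 0.60 ± 1.98 and 0.39 ± 1.78 (SE). Vim measured 327 and 430 against 91.2 and 1505 CPM. Of 23 fibrillar and fibril-associated collagens, 2 were higher and 0 lower in both tip libraries, and the list did not pass (adjusted p = 0.974). Fibroblast markers without collagens (adjusted p = 0.889) were 10.7-fold higher in duct 2 than in duct 1 at the median, in 21 of 21 members. In the collagen and matrix receptors (adjusted p = 0.175), Itga2 measured 27.8 and 51.6 against 126 and 56.0 CPM, and Itga11 2.10 and 4.05 against 4.50 and 13.8 CPM.

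The tip libraries were the closest pair and the duct libraries the farthest apart. Across genes, which are not independent replicates, the log2 correlation was 0.935 between the tip libraries and 0.882 between the duct libraries, against 0.925 for tip 2 with duct 2. The first principal component (43.6% of variance) held the duct libraries at its ends (-62.5 and 78.6), with the tips between (-26.9 and 10.8), and the second (36.9%) separated tip (66.5 and 21.2) from duct (-59.9 and -27.8). Calls depended on the duct libraries: limma called genes in both directions without duct 1 and without duct 2. Most of them were called in only 1 of these fits. In each, the lone duct library was assumed to vary like the tips. Without either tip library 0 genes were called.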

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

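The fibroblast covariate, and the checks of it with other splits and other covariates, were chosen after the data were seen, and the other alternatives before. Of 64 alternatives for counts of genes and lists, 40 stayed within 1.5 times the value reported, 14 were higher, 10 lower and 0 reversed. Of 394 for gene lists 302 kept direction and side of the threshold, 21 newly passed, 24 lost the call and 47 reversed, and of 1422 for named genes 1233 kept both, 140 newly passed and 49 reversed. Of the 1422, 304 concern the 16 rule genes, chosen for non-overlapping groups, whose direction says nothing about stability. Counting error at 1439003 to 1742531 reads limits low genes. Unless stated, the cause was not tested. Where a library was left out, the lone one of its group was assumed to vary like the other group.

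Without a filter limma called 62 genes higher and 32 lower. With the fibroblast covariate it called 194 higher and 84 lower, against 3 and 7 with the same covariate for tip 1 and duct 1 against the rest, and 2 and 1 for tip 1 and duct 2 against the rest. A covariate that only separated duct 1 from duct 2 gave 457 and 184 for tip against duct, and one that only separated the tips 0 genes, so it stays open whether the 194 and 84 reflect stromal RNA or any difference between the ducts. With the fibroblast covariate Pecam1 was -0.15 and Vim -0.30 (log2 fold), and the luminal list had an adjusted p of 0.878. The log2 folds and list p-values given for single settings are those whose direction reversed, except that oxidative phosphorylation genes with a block only lost their call. DESeq2 called 2 lower, with Itga6 -0.043, Pecam1 -0.67, Pdgfra -0.97, Col1a1 -0.76, Col1a2 -0.79, Col3a1 -0.87 and Vim -1.33. edgeR gave Itga6 -0.0063, Pecam1 -0.62, Pdgfra -0.93, Col1a1 -0.72, Col1a2 -0.75, Col3a1 -0.84 and Vim -1.29. Of these genes, those other than Itga6 were highest in duct 2. TMM scaling gave Pecam1 -0.18 and Vim -0.19, median-ratio -0.22 and -0.22, quantile -0.26 and -0.073, the total without mitochondrially encoded and the 10 most abundant genes -0.047 and -0.045, and voom -0.16 and -0.17. A pseudocount of 4 CPM gave Pecam1 -0.028.

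With an estimated correlation 0 lists passed and with fry 0. A mean of at least 5 CPM left 2 lists, and gave reversed adjusted p of 0.953 for basal markers, 0.953 for basement membrane components, 0.958 for AP-1 subunits, 0.84 for immediate early genes and 0.809 for cholesterol synthesis. TMM scaling gave 0.949 for fibroblast markers, 0.949 for collagens and 0.911 for immediate early genes, and a pseudocount of 0.25 CPM 0.988 for the last. Using the title number as a block called 0 genes and 6 lists, with 0.893 for fibroblast markers, 0.784 for collagens and 0.0859 for oxidative phosphorylation genes (correlation within the 2 pairs 0.15, though the numbers do not establish pairing). Genes whose groups did not overlap numbered 416 higher and 363 lower with TMM, 258 and 38 at a mean of at least 5 CPM, where fewer genes were tested, 1552 and 516 at 1.5-fold and 106 and 68 at 4-fold.

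Leaving out each library in turn gave 0 to 698 genes higher, 0 to 311 lower and 3 to 17 lists. Log2 folds ranged from -0.93 to 2.15 for Ptprc, -0.059 to 1.39 for Fos, -1.45 to 0.15 for Epcam, -0.40 to 1.15 for Itga6, -1.13 to 1.15 for Pecam1, -1.62 to 2.30 for Pdgfra, -1.44 to 0.32 for Krt14, -1.42 to 0.13 for Krt8, -1.18 to 0.24 for Krt18, -1.72 to 2.71 for Col1a1, -1.72 to 2.91 for Col1a2, -1.71 to 2.48 for Col3a1, -2.001 to 2.03 for Vim, -3.36 to 0 for Scg2, -2.32 to 0.27 for Sox10 and -1.66 to 0.046 for Gbp3. Adjusted p of lists ranged from 0.0908 to 0.618 for luminal markers, 0.574 to 0.937 for prostate secretory genes, 3.3e-08 to 0.342 for fibroblast markers, 7.0e-07 to 0.746 for matrix remodelling, 0.307 to 0.574 for AP-1 subunits, 0.623 to 0.889 for immediate early genes, 0.104 to 0.48 for cholesterol synthesis, 0.574 to 0.996 for chemokines, 0.0614 to 0.897 for mitochondrially encoded genes, 9.0e-05 to 0.932 for smooth muscle, 1.4e-07 to 0.912 for neural markers, 0.0247 to 0.372 for basement membrane, 0.0192 to 0.523 for FGF response, 1.5e-04 to 0.932 for mesenchymal genes, 0.0124 to 0.996 for squamous genes, 0.0124 to 0.641 for ribosomal proteins, 0.00796 to 0.877 for basal markers, 2.7e-09 to 0.275 for endothelial, 9.0e-04 to 0.754 for immune markers, 1.1e-04 to 0.478 for collagens and 0.523 to 0.932 for nuclear-retained RNAs.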

Other observations

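The tests of collagen, mitosis, the median shift and the Iapp reads, and the choice of the islet, beta-oxidation and actin lists, were made after the results they bear on had been seen; the single values of beta-oxidation and actin members and of 22 islet genes had not been looked at, although 1 of the 22, Chgb, belongs to the neural list, whose excess in duct 2 was known.

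Lists of developmental signalling genes leaned both ways, and none of those given here passed the list test. TGF-beta and BMP pathway genes leaned lower in tip, with 16 of 27 members negative (camera adjusted p = 0.2002), and so did FGF and ERK response genes (adjusted p = 0.421) and Notch pathway genes (adjusted p = 0.595), although the medians of the latter 2 lists were above 0. Of 30 Wnt pathway genes 14 were higher in both tip libraries and 2 lower (camera adjusted p = 0.189), among them the receptors Fzd2 (71.6 and 40.2 CPM in tip, 8.30 and 19.1 CPM in duct) and Fzd7 (140.4 and 90.7 against 33.8 and 65.2 CPM), and the feedback inhibitors Nkd1 (40.3 and 36.7 against 11.5 and 23.7 CPM) and Rnf43 (110 and 59.7 against 44.0 and 14.5 CPM). These named members had the smallest p of the list. Axin2 overlapped between the groups (47.3 and 25.3 against 19.15 and 31.65 CPM), and Tcf7 was lower in both tip libraries (19.5 and 20.7 against 34.45 and 23.75 CPM). Hedgehog pathway genes (adjusted p = 0.214) included the receptor component Smo (107.0 and 122 against 55.5 and 59.9 CPM) and the coreceptors Boc (166 and 157 against 77.2 and 104.1 CPM) and Cdon (95.9 and 83.2 against 47.2 and 50.7 CPM). Of 25 prostate bud and progenitor genes 9 were higher and 1 lower in both tip libraries (adjusted p = 0.579), against 5099 and 1986 of all 17865 tested genes. The list included Bmp7 at 126 and 105 against 59.3 and 36.9 CPM, Aldh1a1 at 129 and 98.7 against 67.6 and 48.7 CPM and the posterior homeobox gene Hoxb13 at 48.6 and 18.4 against 11.5 and 7.25 CPM. Basal epithelial markers (adjusted p = 0.889) included Ngfr (108 and 77.5 against 51.0 and 40.2 CPM), Cdh3 (181 and 127 against 100 and 58.6 CPM) and Jag2 (306 and 211 against 177 and 94.9 CPM).

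Matrix genes went both ways. Thbs1, encoding thrombospondin 1, measured 3225 and 6621 CPM in tip against 11780 and 10700 CPM in duct, and Tgm2, a crosslinking transglutaminase, 368 and 211 against 101 and 129 CPM, in a list that did not pass (adjusted p = 0.694). Of the YAP and TAZ targets (adjusted p = 0.311), Tead1 measured 415 and 511 against 1005 and 638 CPM and Ctgf 45.9 and 62.0 against 86.1 and 87.6 CPM. The AP-1 subunit Atf3 measured 1999 and 1057 against 830 and 520 CPM in a list with an adjusted p of 0.889, and the squamous genes (adjusted p = 0.694) Tgm3 13.9 and 17.8 against 3.85 and 2.00 CPM and Dsc2 223 and 155 against 124 and 56.0 CPM. The 30 lists that did not pass had adjusted p from 0.147 (endothelial markers) to 0.974. In 9 lists the test leaned lower while the median log2 fold was above 0. The red cell list was not tested.

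Collagen and fibroblast RNA varied widely within each group, Col1a1 by 21.6-fold between the duct libraries and 3.51-fold between the tip libraries. Library scaling is argued against, since the largest change another scaling made to the log2 ratio of duct 2 to duct 1 was 0.0819. The fibroblast markers without collagens were also higher, with a median log2 ratio of duct 2 to duct 1 of 3.42, while basal markers were lower at -1.30, so a varying share of RNA from fibroblast-like cells is a candidate source, although the sort removed cells positive for the product of Pdgfra. Of the 4 most abundant markers Vim, Pdgfra and Fbln1 (79.2, 195, 38.3 and 364 CPM in tip 1, tip 2, duct 1 and duct 2) followed, but Dcn, the most abundant, did not (2529, 2656, 2002 and 2294 CPM). All 21 markers had a read in each library and 1, Vim, is also in the list of mesenchymal genes; because of Dcn, a stromal source cannot be told apart from collagen transcription in the sorted cells.

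With the deposited scaling, mitosis RNA was higher in both tip libraries. The ratio of tip 1, the lower of them, to duct 2, the higher duct library, was 1.29 (95% counting interval 1.13 to 1.47). It was 1.19 (1.04 to 1.35) with the total without mitochondrially encoded and the 10 most abundant genes. With TMM that ratio was 1.06 (0.927 to 1.20) and with median-ratio factors 1.03 (0.902 to 1.17). Counting error therefore stays open for that pair, as the interval included 1 under some scalings and not under others. Duct 2, the richest in fibroblast markers, held 0.776 times the mitosis RNA of tip 1 (0.682 to 0.883) as deposited. With the total without mitochondrially encoded and the 10 most abundant genes it held 0.841 times (0.739 to 0.958), but 0.948 (0.832 to 1.08) with TMM. RNA from dividing fibroblast-like cells therefore cannot be told apart either. Members that rise and fall together by chance remain open. For tip 1 and duct 1 against tip 2 and duct 2 the preset camera p (2.84e-07) was smaller than for tip against duct (7.07e-06). The camera adjusted p of 0.917 under an estimated correlation cannot decide this, because that correlation was estimated from 2 libraries per group. A difference in proliferation between tip and duct stays open as an untested biological explanation.

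Duct 2 alone held transcripts of pancreatic islet hormones: 311 reads of Ins2, 86 of Ins1, 102 of Iapp and 4 of Gcg, with 0 in the other 3 libraries (reads may be split between Ins1 and Ins2, which are similar). Transcripts of the insulin genes alone are argued against by the 102 Iapp reads. Of 22 listed islet genes not looked at before, 7 stood out in duct 2 (at least 3 reads and over 2 times each other library), among them Slc30a8 with 10 reads and G6pc2 with 7, against 4.17% of all genes with a read, and without Chgb it was 6 of 21. The bounds set beforehand were 8 or more for islet RNA and 2 or fewer for insulin transcription without it. At 7, that test met neither bound. Counting also those looked at before, 13 of all 30 listed islet genes stood out in duct 2. Insulin transcription with no other islet RNA is therefore argued against for this library. RNA from islet cells, the candidate source, and transcription of several islet genes in the sorted cells cannot be told apart by that test. The labels describe dissected prostate lobes, and how islet RNA could have reached this library was not tested. Of all 30 listed islet genes, 14 had a read in another library and 3 are in the neural list (Scg2, Chga and Chgb, of which Chgb is 1 of the 7); Isl1, 1 of the 7, was also high in tip 2 (18.9 CPM, against 42.8 CPM in duct 2).

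A pair of further hypotheses was tested on lists written from general knowledge after the genes with the smallest p had been read. Fatty acid beta-oxidation genes were positive in 24 of 24 members and higher in both tip libraries in 14 (camera p = 0.00273 preset, and p = 0.259 with an estimated correlation), while the other splits gave preset p of 0.809 and 0.153. Of all tested genes 63.1% were positive with the deposited scaling. Actin cytoskeleton genes linked to the transcription factor SRF were lower in both tip libraries in 14 of 30 members, with 4 positive (p = 2.47e-07, preset; p = 0.256 with an estimated correlation), but tip 1 and duct 2 against the rest gave 3.77e-05. Neither hypothesis is settled, as both required an estimated-correlation p under 0.05, which 2 libraries per group may be too few to give.

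Leaving the mitochondrially encoded and 10 most abundant genes out of the total moved the median log2 fold from 0.198 to 0.147, which lies between the bounds set for that test. The 10 most abundant genes took 7.60, 9.10, 9.76 and 14.8% of signal in tip 1, tip 2, duct 1 and duct 2. Lars2 took 0.137, 0.145, 0.182 and 1.57%, and ribosomal RNA genes 3.08, 3.75, 3.60 and 7.74%. Cd3e, a T cell gene, measured 131, 88.4, 61.2 and 68.5 CPM, while Ptprc was at most 12.6 CPM.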
